A study of Mus musculus with 6 samples.

How the data were processed

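RNA sequencing libraries of mouse uterus were compared between 3 control and 3 Rptor cKO samples, grouped by the genotype in the sample labels. The deposited table holds FPKM values made by the authors, with 1 line per gene symbol and 1 column per library, and replicates were not pooled. Per the submitters' processing notes, HISAT2, HTSeq 0.13.5, Cufflinks and DESeq2 1.30.1 were used with the genome build GRCm38.p6. The role of each tool, the annotation release and any filter are not given in the sources used here. All 24804 genes had a value listed in each of the 6 libraries.

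The FPKM values kept traces of whole reads. Within a gene, the values of the 6 libraries were whole multiples of 1 step after 1 factor per library was applied, for 22287 of 22289 genes with a value in at least 2 libraries. With a tolerance of 0.01 reads, 100% of their values above 0 came out whole. Gene spans of 623 genes in the RefSeq table of GRCm38.p6 set the scale, and the denominator of the FPKM values came to about 33700000, 38900000 and 38200000 fragments in control replicates 1, 2 and 3 and 34600000, 38000000 and 35000000 in Rptor cKO replicates 1, 2 and 3. The recovered reads summed to between 96.25% and 97.53% of it. A count of 0 allows up to 3 reads, which on a gene of 2 kb is 0.0385 to 0.0446 FPKM, counting error only. Of the symbols, 23637 were found in the RefSeq table, which gave the coordinates. Between replicates of a group the recovered reads differed by a chi-square per degree of freedom of 18.6 to 78.6, and no pair of replicates was taken to be 1 library deposited again.

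Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with a pseudocount of 1, an empirical Bayes variance trend and the genotype group as the only term. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, and p-values were adjusted by the Benjamini-Hochberg method, two-sided, with calls at an adjusted p under 0.05. Each of 51 gene lists (27 of pathways and 24 of cell types) was counted, and the 41 with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over lists. Beside it stand camera with a correlation estimated from the data, which called 0 lists, and fry, which called 19. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Named genes are Rptor and Pgr, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, and up to 3 called members of each list with the largest change, or, where no member of a list was called, its member with the highest mean FPKM. Unnamed, numbered and pseudogene models were left out of the largest changes.

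The procedure was tested on simulated data for Rptor cKO against control, with 12475 genes in the step. Limma recovered 40 of 66 genes changed 1.5-fold (60.6%), 64 of 65 changed 2-fold and 65 of 65 changed 4-fold, and called 8 of 12240 unchanged genes. Limma voom recovered 46, 64 and 65 of these. In the simulation 12240 of the 12475 genes were unchanged and genes varied independently, while in the data 39.2% of tested genes were called. Simulated genes of similar level also shared the same spread, so these rates may not hold for the data. The alternatives were pseudocounts of 0.1 and 5, no filter, a minimum mean of 5 FPKM, 3 other scalings, 3 other variance models, the replicate number as a block, 2 other thresholds and leaving out each library. Limma voom on the recovered reads and the adipose list as a covariate were added after the data were seen, as were 14 further gene lists. Tests on counts and on annotation terms were planned only for a table that carries them and were not run. Summaries and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.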

Results

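RNA was sequenced from the uteri of ovariectomized mice, whose ovaries had been removed so that hormone exposure could be set by injection. After 14 days of recovery each mouse received 100 ng of estradiol, the main ovarian estrogen, and the uterus was taken 24 h later, in the phase in which estrogen drives the uterine epithelium to proliferate. The control group carried floxed alleles of Rptor and no Cre recombinase (3 libraries). The Rptor conditional knockout group (Rptor cKO, 3 libraries) carried the same floxed alleles together with Cre expressed from the progesterone receptor gene Pgr, which is active in uterine epithelium, stroma and muscle. Rptor encodes Raptor, the scaffold subunit of mTORC1, a kinase complex that couples nutrients and growth factors to anabolic metabolism. The comparison asked which genes differed between these genotypes 24 h after estradiol. Every library was taken after estradiol, so the response to it was not measured. Cre and its insertion in Pgr were present only in the Rptor cKO, so their effects cannot be told apart from loss of Rptor. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these samples, which may be partly technical. Levels are given in FPKM (fragments per kilobase of gene length, scaled to the library's total) as mean ± SD with n = 3 libraries per group. Depth lay between about 33700000 and 38900000 fragments per library, at which 3 reads on a gene of 2 kb correspond to 0.0385 to 0.0446 FPKM. Of 24804 genes listed, 12552 had a mean of at least 1 FPKM and were tested with limma on log2(FPKM + 1), a scale on which log2 fold changes of low genes are understated.

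The targeted gene was lower in every library labelled Rptor cKO than in every control library. Rptor (chromosome 11, 119602905 to 119899591, GRCm38.p6) stood at 3.50 ± 0.60 FPKM in controls, with libraries from 2.99 to 4.15, and at 2.27 ± 0.19 FPKM in the Rptor cKO, with libraries from 2.08 to 2.47. The mean was 64.9% of control (log2 fold change −0.45, SE 0.13, limma adjusted p = 0.028). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow. The Rptor call was lost without control replicate 1 (log2 fold change −0.35, adjusted p = 0.069), control replicate 3 (−0.47, adjusted p = 0.078), Rptor cKO replicate 1 (−0.41, adjusted p = 0.10) or Rptor cKO replicate 2 (−0.45, adjusted p = 0.076). The deposited value counts the whole gene, so reads from exons outside the floxed part and from cells without Cre remain in it. Pgr (chromosome 9, 8898900 to 8968611), one copy of which carries the Cre insertion in the knockout group, was higher, at 7.71 ± 1.17 FPKM in controls and 10.8 ± 0.75 FPKM in the Rptor cKO (log2 fold change 0.45, SE 0.12, adjusted p = 0.023). That call was lost without control replicate 2 (0.37, adjusted p = 0.064), control replicate 3 (0.42, adjusted p = 0.083), Rptor cKO replicate 1 (0.40, adjusted p = 0.090) or Rptor cKO replicate 2 (0.48, adjusted p = 0.051). The estrogen receptor gene Esr1, looked up after the values were seen, measured 58.0 ± 3.78 FPKM in controls and 56.9 ± 1.96 FPKM in the Rptor cKO (log2 fold change −0.02, SE 0.083, adjusted p = 0.83).

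Many genes differed between the groups: 4923 of the 12552 genes (39.2%) differed, 2084 higher and 2839 lower in the Rptor cKO. On the log2(FPKM + 1) scale, at least a 2-fold change was reached by 840 of them, 398 higher and 442 lower. By mean FPKM some called genes outside this count differed more, such as Lgr5, 4.41-fold higher in controls (log2 fold change −0.99). The largest falls on the log2(FPKM + 1) scale were in Adgrg7, an adhesion G protein-coupled receptor gene, and in Hdc, which encodes the enzyme that makes histamine. Adgrg7 (chromosome 16, 56724609 to 56796006) dropped from 25.7 ± 3.26 to 0.553 ± 0.86 FPKM. Hdc (chromosome 2, 126593659 to 126624025) dropped from 19.4 ± 6.02 to 1.06 ± 0.63 FPKM. Their log2 fold changes were −4.23 (SE 0.33, adjusted p = 0.00054) and −3.31 (SE 0.29, adjusted p = 0.00072). Crabp1, a retinoic acid binding protein gene (chromosome 9, 54764748 to 54773110), changed by −3.28 (SE 0.21, adjusted p = 0.00031), and the glutathione peroxidase gene Gpx2 (chromosome 12, 76792335 to 76795554) by −3.25 (SE 0.33, adjusted p = 0.00091). Pigr, which encodes the receptor that carries immunoglobulin across epithelium, changed by −2.96 (SE 0.37, adjusted p = 0.0017), Calb1, a calcium binding protein gene, by −2.93 (SE 0.61, adjusted p = 0.0093), and the cornified envelope gene Sprr1a by −2.78 (SE 0.32, adjusted p = 0.0013). Among the 10 largest falls were also 3 genes of sterol synthesis, Fdps, Sqle and Mvd.

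On the log2(FPKM + 1) scale the largest rise was in Gpnmb, a glycoprotein gene of lysosomes and macrophages (chromosome 6, 49036518 to 49058182). Gpnmb went from 3.50 ± 1.93 to 41.9 ± 11.2 FPKM (log2 fold change 3.30, SE 0.31, adjusted p = 0.00081). Next came Mmp3, a matrix metalloproteinase gene (chromosome 9, 7445822 to 7455975), from 3.72 ± 2.45 to 39.7 ± 4.87 FPKM (3.24, SE 0.35, adjusted p = 0.0010). Mmp3 lies close to Pgr (chromosome 9, 8898900 to 8968611), the site of the Cre insertion. An effect of that insertion on Mmp3 cannot be told apart from loss of Rptor. Retnla (chromosome 16, 48842609 to 48844461) followed, from 1.41 ± 0.43 to 20.03 ± 8.83 FPKM (3.04, SE 0.33, adjusted p = 0.0011). Scnn1b, a subunit of the epithelial sodium channel (chromosome 7, 121865038 to 121918728), went from 0.804 ± 0.16 to 9.91 ± 1.32 FPKM (2.59, SE 0.13, adjusted p = 0.00023), and Bex4 (chromosome X, 136138996 to 136140443) from 2.83 ± 0.24 to 22.5 ± 5.40 FPKM (2.60, SE 0.16, adjusted p = 0.00031). The other genes among the 10 largest rises were the adipocyte genes Cfd (2.68, SE 0.54) and Plin4 (2.65, SE 0.17), Tmprss11b (2.67, SE 0.31), the water channel gene Aqp8 (2.64, SE 0.42) and the haptoglobin gene Hp (2.53, SE 0.37), all with an adjusted p of at most 0.0087. By the ratio of mean FPKM, Aqp8 (15.2), Retnla (14.2) and Scnn1b (12.3) rose more than Gpnmb (12.0). Adipose markers, which include Cfd and Plin4, rose in the same libraries in 9 of 10 cases (median 2.01). The rule that chose these 20 genes required that all libraries of one group lie above all of the other, which 6617 of the tested genes did (52.7%, where chance gives 10%).

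**Figure D1:**
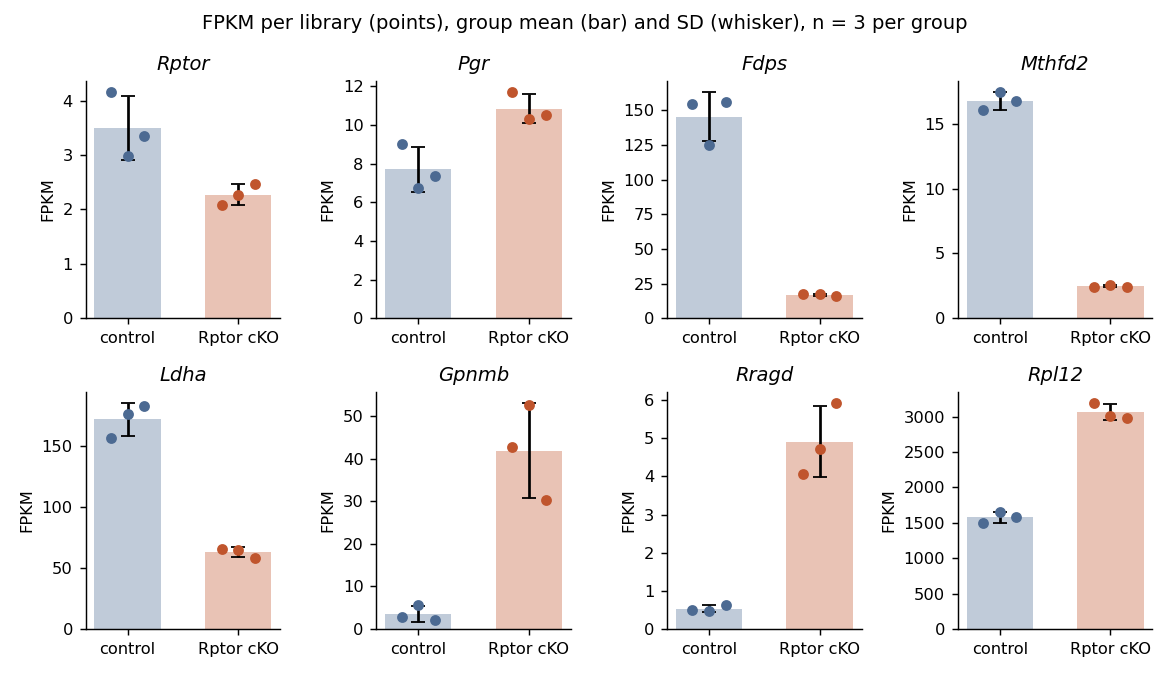
FPKM of 8 genes in each library (points), with the group mean (bar) and SD (whisker), n = 3 libraries per group; each panel has its own axis starting at 0. Rptor fell to 64.9% of control, Fdps, Mthfd2 and Ldha fell, and Pgr, Gpnmb, Rragd and Rpl12 rose, with no overlap between the groups.

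Genes of sterol synthesis fell as a block. All 25 measured members of the cholesterol synthesis list, targets of the transcription factor SREBP2, fell (median −1.86), and 25 fell when p-values were adjusted over the list alone. Besides genes of synthesis the list holds genes of sterol uptake and regulation, such as Ldlr, Pcsk9, Insig1 and Srebf2. Fdps, which makes the isoprenoid precursor of sterols (chromosome 3, 89093588 to 89101967), dropped from 145 ± 17.7 to 16.8 ± 0.80 FPKM (log2 fold change −3.03, SE 0.11, adjusted p = 8.2e-05), and squalene epoxidase, Sqle (chromosome 15, 59315092 to 59331193), from 56.1 ± 11.3 to 5.98 ± 1.25 FPKM (−3.03, SE 0.18, adjusted p = 0.00031). Mvd changed by −2.89 (SE 0.18, adjusted p = 0.00031). The camera test with a preset correlation between genes gave the list an adjusted p of 8.3e-17, and the adjusted p was 0.51 with an estimated correlation. Of 19 measured genes of fatty acid synthesis (SREBP1 targets), 14 fell and 0 rose (median −0.75), with 14 lower and 1 higher when adjusted over the list alone. The desaturase gene Scd2 went from 268 ± 30.4 to 67.6 ± 19.8 FPKM (−2.00, SE 0.20, adjusted p = 0.00086), the elongase gene Elovl6 changed by −1.92 (SE 0.18, adjusted p = 0.00081) and malic enzyme, Me1, by −1.66 (SE 0.10, adjusted p = 0.00031). This list had an adjusted p of 0.00012 by camera and an adjusted p of 0.51 with an estimated correlation. Without control replicate 3, or without Rptor cKO replicate 1, 9 fatty acid genes fell in place of 14, and without control replicate 1, 1 rose.

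Of 26 measured genes of serine and one-carbon metabolism and other targets of the transcription factor ATF4, 20 fell, 2 rose and 4 did not pass (median −0.83; 21 fell and 2 rose when adjusted over the list alone). The number that rose was 1 without control replicate 2, control replicate 3 or Rptor cKO replicate 1, with equal library totals or without a filter on low values. Psat1 of serine synthesis (chromosome 19, 15905123 to 15925059) dropped from 83.1 ± 3.11 to 12.9 ± 5.11 FPKM (−2.66, SE 0.23, adjusted p = 0.00070). The mitochondrial folate enzyme gene Mthfd2 (chromosome 6, 83305704 to 83326011) dropped from 16.8 ± 0.68 to 2.47 ± 0.10 FPKM (−2.35, SE 0.087, adjusted p = 8.2e-05), and Phgdh changed by −1.65 (SE 0.16, adjusted p = 0.00086). Camera gave an adjusted p of 1.5e-07 for this list, and the adjusted p was 0.13 with an estimated correlation. In the list of pentose phosphate and nucleotide synthesis 16 of 27 genes fell and 0 rose (median −0.44; 21 fell and 1 rose when adjusted over the list alone). Among them the ribonucleotide reductase subunit gene Rrm2 changed by −1.68 (SE 0.31, adjusted p = 0.0066) and Pgd by −1.31 (SE 0.096, adjusted p = 0.00045). The list had an adjusted p of 6.3e-06 by camera and an adjusted p of 0.51 with an estimated correlation. In the list of glycolysis and HIF1A targets 16 of 27 genes fell and 3 rose (median −0.53; the same numbers when adjusted over the list alone), and 1 rose without control replicate 3 or Rptor cKO replicate 2. Lactate dehydrogenase A, Ldha, dropped from 172 ± 13.5 to 63.0 ± 4.19 FPKM (−1.43, SE 0.095, adjusted p = 0.00034), Pgk1 changed by −1.15 (SE 0.096, adjusted p = 0.00066) and the hypoxia-inducible Egln3 by −2.66 (SE 0.30, adjusted p = 0.0012). Camera gave an adjusted p of 0.0041, and the adjusted p was 0.51 with an estimated correlation. General epithelial markers fell in the same libraries by a median of −0.57. A smaller share of epithelium was not tested as a source for the ATF4, nucleotide, glycolysis or fatty acid lists.

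Genes of lysosomes and autophagy, targets of TFEB and TFE3, moved the other way: 23 of 41 rose, 2 fell and 16 did not pass (median 0.46; 24 rose and 2 fell when adjusted over the list alone). Beside Gpnmb, Rragd, which encodes a Rag GTPase that recruits mTORC1 to lysosomes (chromosome 4, 32982998 to 33022180), went from 0.531 ± 0.090 to 4.91 ± 0.94 FPKM (log2 fold change 1.94, SE 0.14, adjusted p = 0.00045). The acid glucosidase gene Gaa went from 22.0 ± 0.48 to 58.6 ± 2.50 FPKM (1.37, SE 0.076, adjusted p = 0.00031). Camera gave the list an adjusted p of 6.3e-07, and the adjusted p was 0.39 with an estimated correlation. Markers of macrophages and monocytes, cells rich in lysosomes, rose in the same libraries in 14 of 18 cases (median 1.60). Among 32 measured components and inputs of mTORC1, 5 rose and 6 fell, as they did when adjusted over the list alone (camera adjusted p = 0.95, upward, while the list median was below 0). They included Rragd, Flcn, a regulator of Rag GTPases (0.96, SE 0.097, adjusted p = 0.00091), and the stress-induced mTORC1 inhibitor Sesn2 (−1.10, SE 0.23, adjusted p = 0.0094). Without control replicate 3, or without Rptor cKO replicate 1, 3 of these components fell in place of 6, and without control replicate 2 or Rptor cKO replicate 2, 4 did.

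Transcripts for the proteins of the ribosome rose while those for building it fell. Of 81 genes of cytosolic ribosomal proteins, 61 rose, 1 fell and 19 did not pass (median 0.53; 67 rose and 1 fell when adjusted over the list alone). Rpl12 went from 1576 ± 76.8 to 3061 ± 114 FPKM (0.96, SE 0.10, adjusted p = 0.00097), Rpl18a changed by 1.06 (SE 0.12, adjusted p = 0.0014) and Rpl23 by 1.01 (SE 0.12, adjusted p = 0.0016). The member that fell, Rps27l, is a paralog of Rps27 and was named after its value was seen (−0.92, SE 0.15, adjusted p = 0.0040). Reads of these genes can be shared with their many processed pseudogenes. Camera gave an adjusted p of 8.3e-17, and the adjusted p was 0.54 with an estimated correlation. The list median was 0.23 after quantile normalization, with 42 genes that rose. Without a filter on low values 24 of 84 rose, without Rptor cKO replicate 1, 35 rose, and without Rptor cKO replicate 2, 39 rose. Of 37 ribosome biogenesis genes, 27 fell and 0 rose, also when adjusted over the list alone (median −0.48). Bop1 changed by −1.12 (SE 0.088, adjusted p = 0.00054), Noc4l by −1.10 (SE 0.10, adjusted p = 0.00080) and Nhp2 by −1.04 (SE 0.13, adjusted p = 0.0016). That list had an adjusted p of 6.3e-07 by camera and an adjusted p of 0.39 with an estimated correlation. In the same libraries general epithelial markers fell by a median of −0.57. Whether a smaller share of epithelium contributed to the fall of ribosome biogenesis genes was not tested.

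Nuclear genes for the subunits of oxidative phosphorylation fell in 48 of 74 cases and rose in 0 (median −0.49; 57 fell when adjusted over the list alone). Cox5a dropped from 51.8 ± 7.84 to 22.7 ± 2.83 FPKM (−1.15, SE 0.14, adjusted p = 0.0016), and Uqcrq changed by −1.09 (SE 0.18, adjusted p = 0.0045). Camera gave an adjusted p of 7.0e-10, and the adjusted p was 0.55 with an estimated correlation. Without control replicate 3, 28 subunit genes fell. Of 13 regulators of mitochondrial biogenesis, 1 rose (Twnk, 0.54, SE 0.10, adjusted p = 0.0075) and 2 fell (median −0.16, camera adjusted p = 0.53), and 1 rose and 1 fell when adjusted over the list alone. The number that fell at the limma threshold was 0 without control replicate 2, Rptor cKO replicate 1 or Rptor cKO replicate 2, 1 without control replicate 3 and 3 without control replicate 1. Genes of endoplasmic reticulum stress and the unfolded protein response fell in 11 of 21 cases and rose in 0 (median −0.36; 11 fell and 1 rose when adjusted over the list alone), among them the chaperone genes Dnajb11 (−1.10, SE 0.11, adjusted p = 0.00085) and Hyou1 (−0.78, SE 0.16, adjusted p = 0.0099). Their list had an adjusted p of 0.0036 by camera and an adjusted p of 0.55 with an estimated correlation. With the adipose list as a covariate its adjusted p was 0.26 (median −0.19), and 2 of its genes rose without control replicate 1 and 1 without Rptor cKO replicate 3. The median fall of general epithelial markers in the same libraries (−0.57) was larger than that of the oxidative phosphorylation or endoplasmic reticulum list. A smaller share of epithelium was not tested as a source for either.

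**Figure D2:**
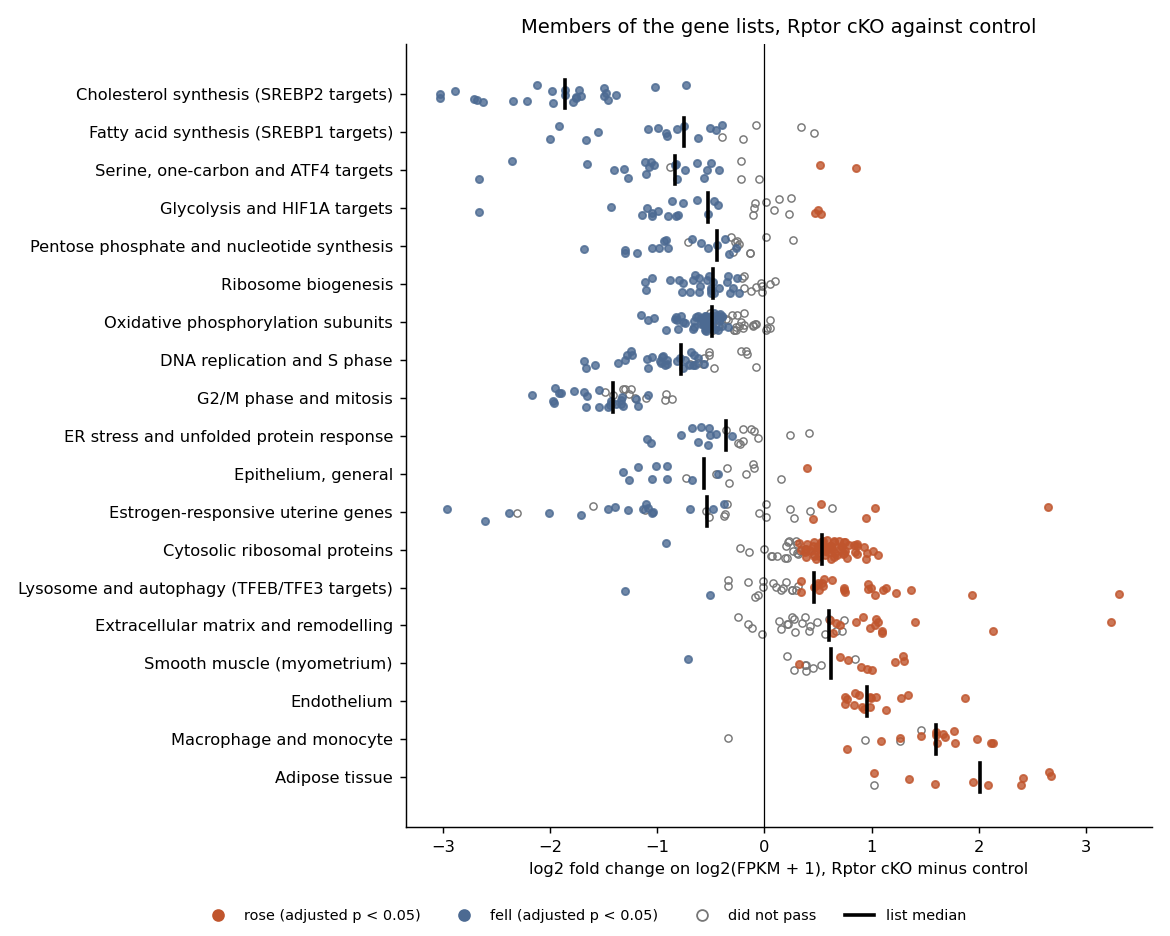
Log2 fold change of each tested member of 19 gene lists on the log2(FPKM + 1) scale, Rptor cKO minus control (filled points passed at an adjusted p under 0.05, open points did not, black bars are list medians; vertical scatter within a row is arbitrary). List medians run from −1.86 for cholesterol synthesis to 2.01 for adipose markers.

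Cell cycle genes fell, but unequally among the 3 Rptor cKO libraries. Of 40 genes of DNA replication and S phase, 29 fell and 0 rose (median −0.78; 33 fell when adjusted over the list alone). Cyclin E1, Ccne1, dropped from 9.65 ± 1.84 to 2.42 ± 1.04 FPKM (−1.67, SE 0.23, adjusted p = 0.0023) and the origin recognition gene Orc1 from 4.82 ± 0.42 to 1.00 ± 0.60 FPKM (−1.58, SE 0.20, adjusted p = 0.0018). Of 35 genes of G2/M phase and mitosis, 23 fell and 0 rose (median −1.41; 29 fell when adjusted over the list alone). The centromere gene Cenpa dropped from 29.2 ± 4.31 to 7.23 ± 4.03 FPKM (−1.98, SE 0.31, adjusted p = 0.0035) and Cdc20 from 50.4 ± 11.6 to 13.6 ± 9.01 FPKM (−1.96, SE 0.39, adjusted p = 0.0083). Camera gave adjusted p-values of 9.6e-08 for S phase and 8.4e-07 for G2/M, and both had an adjusted p of 0.55 with an estimated correlation. Fry called neither list (adjusted p = 0.053 for S phase and 0.084 for G2/M). The G2/M list mean lay 1.77 and 2.15 log2 units below the control mean in Rptor cKO replicates 1 and 2 and 0.42 below it in replicate 3, and the S phase list mean lay 1.01, 1.11 and 0.39 below it. The proliferation marker Mki67, picked after its values were seen, measured 10.3, 6.80 and 34.7 FPKM in those libraries and 34.0 ± 11.9 FPKM in controls (−1.20, SE 0.53, adjusted p = 0.11). Without Rptor cKO replicate 3 its log2 fold change was −1.85 (adjusted p = 0.0026). Without Rptor cKO replicate 3, all 35 G2/M genes and 38 S phase genes fell. Without a filter on low values, 8 G2/M genes and 17 S phase genes fell. The G2/M count was 10 without control replicate 1, 8 without control replicate 3, 9 without Rptor cKO replicate 1 and 12 without Rptor cKO replicate 2, and the S phase count was 14 without control replicate 3 and 17 without control replicate 2, Rptor cKO replicate 1 or Rptor cKO replicate 2. Cell cycle inhibitors and p53 targets fell in 9 of 22 cases and rose in 2, also when adjusted over the list alone (median −0.34, camera adjusted p = 0.055). The list of inhibitors was called without control replicate 1 (adjusted p = 0.035), Rptor cKO replicate 1 (adjusted p = 0.045) or Rptor cKO replicate 2 (adjusted p = 0.046). It was also called with equal library totals (adjusted p = 0.048), with the adipose list as a covariate (adjusted p = 0.047) and without a filter on low values (adjusted p = 0.0028). The number of inhibitors that rose was 1 without control replicate 2, control replicate 3 or Rptor cKO replicate 1. Cdkn1a, which encodes the inhibitor p21, changed by −1.10 (SE 0.099, adjusted p = 0.00074). General epithelial markers fell by a median of −0.57 in the same libraries. Whether a smaller share of epithelium contributed to the fall of cell cycle genes between the groups was not tested.

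Estrogen-responsive uterine genes moved in both directions, with 16 of 36 lower, 5 higher and 15 not passing (median −0.53; 16 lower and 6 higher when adjusted over the list alone). Besides Pigr, Sprr2a3, a small proline-rich protein gene of a family with near-identical copies, dropped from 84.7 ± 10.03 to 19.1 ± 17.1 FPKM (−2.61, SE 0.72, adjusted p = 0.027), and Aqp8 rose, while the lactoferrin gene Ltf, picked after its value was seen, measured 408 ± 50.7 and 485 ± 97.7 FPKM (adjusted p = 0.28). The Sprr2a3 call was lost without control replicate 1 (−2.69, adjusted p = 0.065), 2 (−2.53, adjusted p = 0.069) or 3 (−2.61, adjusted p = 0.080), and its log2 fold change was −1.69 without Rptor cKO replicate 3. Camera gave the list an adjusted p of 0.025, and the adjusted p was 0.55 with an estimated correlation. The call was also lost without control replicate 1 (adjusted p = 0.078), control replicate 2 (adjusted p = 0.055) or Rptor cKO replicate 3 (adjusted p = 0.081), and at a minimum mean of 5 FPKM (adjusted p = 0.22). The number that rose was 2 without a filter on low values, 3 without control replicate 1 or Rptor cKO replicate 1 and 2 without control replicate 3 or Rptor cKO replicate 2. Of 14 components of estrogen receptor signalling, 1 rose (Klf9, 0.84, SE 0.11, adjusted p = 0.0021) and 1 fell (Gper1, −1.02, SE 0.16, adjusted p = 0.0037), or 2 without Rptor cKO replicate 3. Of 17 progesterone-responsive genes, 5 rose and 1 fell (camera adjusted p = 0.071). Camera called the progesterone list without Rptor cKO replicate 1 (adjusted p = 0.016) or 2 (adjusted p = 0.049), with quantile normalization (adjusted p = 0.029) and at a minimum mean of 5 FPKM (adjusted p = 0.044). Of its members Zbtb16 changed by 0.86 (SE 0.13, adjusted p = 0.0031) and the co-chaperone gene Fkbp4 by −0.72 (SE 0.085, adjusted p = 0.0014). Both of these lists had the same counts when adjusted over the list alone. Of 25 genes of water, ion and nutrient transport, 7 rose and 9 fell, as when adjusted over the list alone (camera adjusted p = 0.75). Scnn1b and Aqp8 were among those that rose. Carbonic anhydrase 2, Car2 (chromosome 3, 14886269 to 14900770), dropped from 919 ± 49.9 to 176 ± 54.8 FPKM (−2.42, SE 0.21, adjusted p = 0.00067).

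Markers of epithelium were lower. Of 18 general epithelial markers 9 fell, 1 rose and 8 did not pass (median −0.57; 10 fell and 1 rose when adjusted over the list alone), and 0 rose at the limma threshold without Rptor cKO replicate 1. The tight junction gene Cldn7 dropped from 219 ± 10.4 to 87.3 ± 7.97 FPKM (−1.32, SE 0.094, adjusted p = 0.00041), Cdh1 changed by −1.26 (SE 0.18, adjusted p = 0.0024) and Krt8 by −1.18 (SE 0.11, adjusted p = 0.00080). Krt18, the partner keratin of Krt8 and picked after its values were seen, measured 232 ± 3.903 and 216 ± 5.84 FPKM (−0.11, adjusted p = 0.30). Camera gave the list an adjusted p of 0.0022, and the adjusted p was 0.51 with an estimated correlation. Luminal markers fell in 6 of 10 cases and rose in 0, also when adjusted over the list alone (median −0.63, camera adjusted p = 0.064), including Calb1 and Lpar3, a receptor gene for lysophosphatidic acid (−1.42, SE 0.27, adjusted p = 0.0067). The luminal list was called without Rptor cKO replicate 3 (1 rose, adjusted p = 0.023), with median-of-ratios scaling (adjusted p = 0.043), with the adipose list as a covariate (adjusted p = 0.031) and without a filter on low values (adjusted p = 0.014). Of 6 glandular markers 2 fell and 1 rose, also when adjusted over the list alone (median 0.01, mean −0.23, camera adjusted p = 0.97). Of these 1 fell without control replicate 1, control replicate 3, Rptor cKO replicate 1 or Rptor cKO replicate 2. The epithelial list mean lay 0.59, 0.78 and 0.37 log2 units below the control mean in Rptor cKO replicates 1, 2 and 3, so the library with the smallest fall in cell cycle genes also had the smallest fall in epithelial markers.

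Markers of vessels, macrophages, muscle and fat were higher. All 16 endothelial markers rose, also when adjusted over the list alone (median 0.96), such as Vwf, which encodes von Willebrand factor, from 1.80 ± 0.87 to 9.01 ± 1.73 FPKM (1.87, SE 0.23, adjusted p = 0.0016), and Plvap (1.34, SE 0.27, adjusted p = 0.0087). Of 18 markers of macrophages and monocytes 14 rose and 0 fell (median 1.60; 15 rose when adjusted over the list alone). The growth factor receptor gene Csf1r went from 5.49 ± 3.52 to 23.2 ± 7.50 FPKM (1.99, SE 0.40, adjusted p = 0.0086) and the chemokine receptor gene Ccr2 from 4.25 ± 1.02 to 22.9 ± 9.05 FPKM (2.12, SE 0.31, adjusted p = 0.0027). Without control replicate 3, 8 macrophage markers rose, and without Rptor cKO replicate 1, or without a filter on low values, 9 did. Without Rptor cKO replicate 3, 1 macrophage marker fell. Smooth muscle markers rose in 9 of 18 cases and fell in 1 (median 0.62; 10 rose and 1 fell when adjusted over the list alone), among them Myocd, from 3.70 ± 0.49 to 10.6 ± 1.86 FPKM (adjusted p = 0.0012), and Myh11, from 223 ± 31.3 to 555 ± 137 FPKM (1.29, SE 0.19, adjusted p = 0.0031). Without Rptor cKO replicate 3, 14 of them rose, and 0 fell without that library, control replicate 2, control replicate 3 or Rptor cKO replicate 1. Stromal markers rose in 3 of 20 cases, or 2 when adjusted over the list alone, and fell in 0 (median 0.18), with Pdgfrb at 1.02 (SE 0.10, adjusted p = 0.00093). Adipose markers rose in 9 of 10 cases, also when adjusted over the list alone (median 2.01), with Cfd from 19.2 ± 10.4 to 126 ± 65.9 FPKM and Cidec from 3.03 ± 1.82 to 21.1 ± 10.996 FPKM. The camera adjusted p was 1.7e-07 for endothelium, 1.0e-06 for macrophages, 9.4e-05 for smooth muscle, 0.047 for stroma and 1.1e-05 for adipose markers. With an estimated correlation the adjusted p was 0.53, 0.51, 0.55, 0.57 and 0.51 in the same order. Without Rptor cKO replicate 3, 5 stromal markers rose, and the stromal median was 0.07 without control replicate 1 and 0.33 without control replicate 2. The stromal list was not called without control replicate 1 (adjusted p = 0.23), control replicate 3 (adjusted p = 0.057) or Rptor cKO replicate 2 (adjusted p = 0.14). It was also not called with a pseudocount of 0.1 (adjusted p = 0.054) or without a filter on low values (adjusted p = 0.068).

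**Figure D3:**
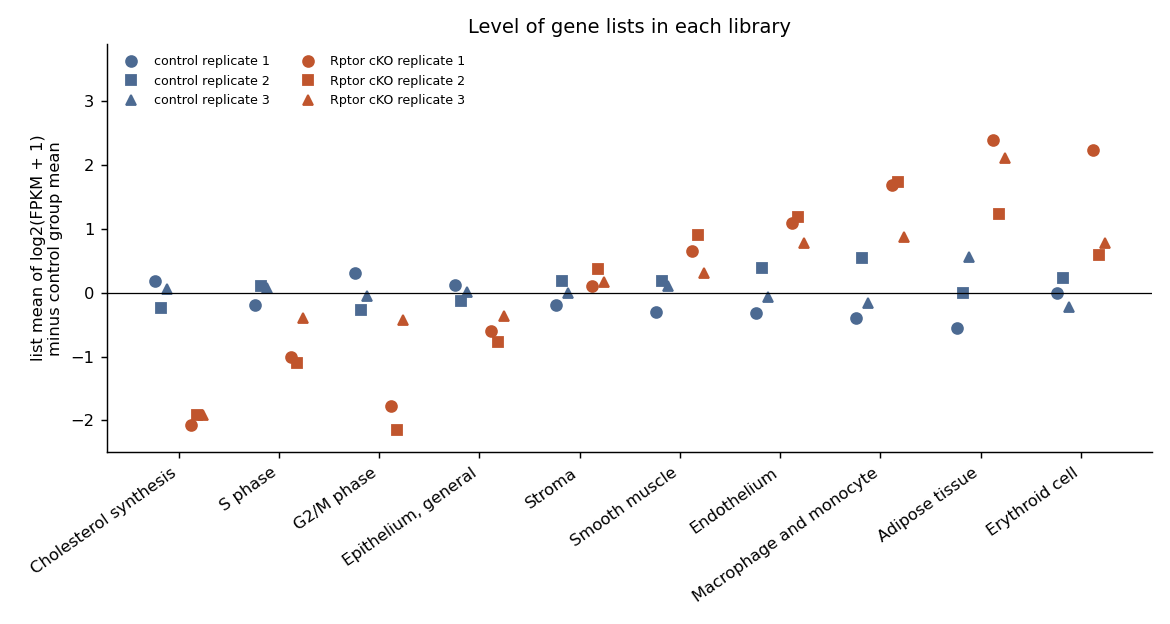
Mean log2(FPKM + 1) over the tested members of 10 gene lists in each of the 6 libraries, minus the mean of the 3 control libraries (blue, control; orange, Rptor cKO; the marker shape gives the replicate number). Rptor cKO replicate 3 lies 0.42 below controls for G2/M genes where replicates 1 and 2 lie 1.77 and 2.15 below, while the 3 libraries lie 1.91 to 2.08 below controls for cholesterol synthesis.

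Genes of extracellular matrix and remodelling rose in 15 of 36 cases and fell in 0, also when adjusted over the list alone (median 0.61). Periostin, Postn, went from 21.8 ± 13.3 to 89.4 ± 25.2 FPKM (2.13, SE 0.43, adjusted p = 0.0085) and the metalloproteinase inhibitor gene Timp3 from 45.2 ± 10.6 to 119.5 ± 10.7 FPKM (SE of the log2 fold change 0.16, adjusted p = 0.0014). Camera gave an adjusted p of 1.2e-06, and the adjusted p was 0.55 with an estimated correlation. Antigen presentation genes rose in 10 of 16 cases and fell in 1 (median 0.75; 12 rose and 1 fell when adjusted over the list alone), with H2-Aa, a class II histocompatibility gene, from 56.6 ± 21.9 to 217 ± 73.7 FPKM (1.93, SE 0.35, adjusted p = 0.0063). This list had an adjusted p of 0.0016 by camera and an adjusted p of 0.55 with an estimated correlation. Without control replicate 3, or without Rptor cKO replicate 2, 6 of its genes rose, and without Rptor cKO replicate 1, 5 did. The number that fell was 0 without control replicate 2 or Rptor cKO replicate 1, at the limma threshold. Both groups were measured in the same libraries in which all endothelial and most macrophage markers rose. Cytokine and chemokine genes rose in 6 of 20 cases and fell in 3 (camera adjusted p = 0.13; 7 rose and 3 fell when adjusted over the list alone). Of these genes 2 rose without control replicate 3 or Rptor cKO replicate 1, and 1 fell without control replicate 1. Camera called this list without control replicate 2 (adjusted p = 0.018) or Rptor cKO replicate 3 (adjusted p = 0.044) and at a minimum mean of 5 FPKM (adjusted p = 0.0081). Of 31 interferon response genes 6 rose and 4 fell (camera adjusted p = 0.53; 4 and 4 when adjusted over the list alone), with 2 that rose without control replicate 1, Rptor cKO replicate 1 or Rptor cKO replicate 2 and 3 without control replicate 2. Oasl1 changed by −1.25 (SE 0.12, adjusted p = 0.00089) and Ifit3 by 0.91 (SE 0.20, adjusted p = 0.012). Immediate early genes rose in 5 of 19 cases and fell in 2, also when adjusted over the list alone (median 0.31, camera adjusted p = 0.049, adjusted p = 0.55 with an estimated correlation), with Klf2 at 1.20 (SE 0.18, adjusted p = 0.0029). The immediate early call was lost without control replicate 1 (adjusted p = 0.073), control replicate 3 (adjusted p = 0.072) or Rptor cKO replicate 2 (adjusted p = 0.13), and 1 of its genes fell without each of these. It was lost too with a pseudocount of 0.1 (adjusted p = 0.054), median-of-ratios scaling (adjusted p = 0.062) or limma voom (adjusted p = 0.053).

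Of 21 genes of IGF and growth factor signalling 6 rose and 2 fell (camera adjusted p = 0.068), with Igf2 from 1.54 ± 0.43 to 5.15 ± 0.66 FPKM (1.28, SE 0.16, adjusted p = 0.0016). Of 21 Wnt signalling genes 5 rose and 3 fell (camera adjusted p = 0.46), with Dkk3 from 8.03 ± 1.38 to 24.5 ± 3.06 FPKM (SE of the log2 fold change 0.14, adjusted p = 0.00085). Counts of both lists were the same when adjusted over the list alone. Of the IGF list 0 genes fell at the limma threshold without control replicate 3, Rptor cKO replicate 1 or Rptor cKO replicate 2, 1 without control replicate 2 and 3 without Rptor cKO replicate 3. Camera called the IGF list without Rptor cKO replicate 2 (adjusted p = 0.049) and at a minimum mean of 5 FPKM (adjusted p = 0.044). Without control replicate 1, control replicate 3 or Rptor cKO replicate 2, 3 Wnt genes rose, and without Rptor cKO replicate 3, 5 fell. Mast cell markers rose in 4 of 5 cases, also when adjusted over the list alone (median 0.58, camera adjusted p = 0.028, adjusted p = 0.51 with an estimated correlation), with Cma1 at 0.80 (SE 0.17, adjusted p = 0.010). That count was 2 without control replicate 1 and 1 without control replicate 3, Rptor cKO replicate 1 or Rptor cKO replicate 2. The mast cell list was not called with quantile normalization (adjusted p = 0.075), without a filter on low values (adjusted p = 0.092) or with limma voom (adjusted p = 0.053). Haemoglobin and other erythroid genes rose in 5 of 6 cases and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.12), with Hbb-bs at 271, 56.8 and 84.6 FPKM in the 3 Rptor cKO libraries against 34.96 ± 9.08 FPKM in controls. Without control replicate 1 or 3, or without a filter on low values, 0 erythroid genes rose at this limma threshold, and without control replicate 2, 1 did. Camera called the erythroid list without Rptor cKO replicate 2 (adjusted p = 0.040). Lymphatic endothelial markers rose in 1 of 7 cases (median 0.65), pericyte markers in 2 of 8 (median 0.32) and T cell and NK cell markers in 1 of 5, where 1 fell (median 0.48). Adjusted over the list alone, 0, 2 and 2 rose. Neutrophil markers fell in 2 of 6 cases, Ly6g and Lcn2, of which Lcn2 is also in the estrogen-responsive list. Mesothelial markers fell in 1 of 8 cases. Both counts were the same when adjusted over the list alone. None of these 5 cell type lists was called by camera with all 6 libraries (adjusted p from 0.054 to 0.77). The lymphatic list was called without control replicate 2 (4 rose, adjusted p = 0.0063) or Rptor cKO replicate 3 (3 rose, adjusted p = 0.0084) and with equal library totals (adjusted p = 0.029). At the limma threshold 0 of its markers rose without any 1 of the other 4 libraries. Without Rptor cKO replicate 3, 3 markers of T cells and NK cells rose, and without a filter on low values 4 of 16 did and their list was called (adjusted p = 0.0028). For pericytes 1 marker rose without control replicate 1, control replicate 2, Rptor cKO replicate 1 or Rptor cKO replicate 2, and 1 mesothelial marker rose without control replicate 2.

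The remaining 10 lists had fewer than 5 members with a mean of at least 1 FPKM and were not given a list test at that filter. Without a filter on low values 8 of them were tested, and the dendritic cell list was called (4 of 8 rose, camera adjusted p = 0.0016). Among their members 2 of 4 dendritic cell markers rose, including Clec10a (1.90, SE 0.19, adjusted p = 0.00091), and 1 of 2 eosinophil markers rose (Ear2, 1.64, SE 0.15, adjusted p = 0.00081). In the B cell and plasma cell list 1 of 4 rose and 1 fell, in the nerve list 1 of 4 rose (Plp1, 0.96, SE 0.14, adjusted p = 0.0030) and 1 fell, and in the ovary list 1 of 2 rose (Inha, 0.96, SE 0.20, adjusted p = 0.0097). In each of the next 3 lists 1 member fell, among 3 mTORC2 components (Mapkap1, −0.31, SE 0.079, adjusted p = 0.020), 4 ciliated cell markers (Foxj1, −0.95, SE 0.19, adjusted p = 0.0088) and 3 skeletal muscle markers (Tnni2, −1.39, SE 0.12, adjusted p = 0.00070). The Mapkap1 call was lost without control replicate 3 (−0.31, adjusted p = 0.069), Rptor cKO replicate 1 (−0.33, adjusted p = 0.059) or Rptor cKO replicate 2 (−0.28, adjusted p = 0.080). The 1 pancreas marker tested, Cela1 (0.57, SE 0.31, adjusted p = 0.19), and the 2 bladder markers did not pass, and the bladder marker Krt5 stood at 16.8 FPKM in Rptor cKO replicate 1 and at most 0.945 FPKM in the other 5 libraries.

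Libraries grouped by genotype. Pearson correlations of log2(FPKM + 1) across genes were 0.979 to 0.990 within controls, 0.969 to 0.991 within the Rptor cKO and 0.908 to 0.952 between groups, and the first principal component of the 1000 most variable genes held 79.7% of their variance. The number of changed genes was 3020 without control replicate 3, 3040 without Rptor cKO replicate 1 and 3268 without Rptor cKO replicate 2, and 9356 with estimated library weights. With the adipose list mean as a covariate, a setting chosen after the data were seen, limma called 0 genes (1953 at an unadjusted p under 0.05, against 6192 without the covariate, and 4914 called by limma voom without it). Over the 4923 genes the median absolute log2 fold change was 0.60 without the covariate and 0.63 with it, while the median SE was 0.12 and 0.29. With the covariate the list median was −1.72 for cholesterol synthesis, −0.95 for ATF4 targets and 0.97 for endothelium, and camera called 23 lists. With its preset correlation camera called 23 of 41 lists, and 0 of these calls held with an estimated correlation. For the ATF4 list the estimated correlation was −0.033, below the preset 0.01, yet its adjusted p was 0.13. A higher correlation between genes therefore does not account for the loss of that call. Splits of the libraries that mix the genotypes called 7 to 26 lists. The number of called lists thus did not set the real grouping apart. Fry did not call 7 of the 23 lists, among them S phase and G2/M. The other fry adjusted p-values were 0.061 for matrix, 0.070 for smooth muscle, 0.073 for antigen presentation, 0.19 for stroma and 0.11 for immediate early genes.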

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

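The adipose covariate and limma voom were chosen after the data were seen; the other settings were planned. Over 21 settings, the 135 named genes besides Rptor gave the same verdict 2487 times, a weaker one 309 times, a stronger one 3 times and the opposite sign 3 times, and over 22 settings the 41 tested lists did so 789, 49, 34 and 23 times. Camera used neither the variance trend nor the library weights, so under the 3 other variance models its p-values could not change. A threshold of 0.1 could not weaken any call. These tallies therefore overstate how far the settings tested the results.

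Counts moved as follows from 4923 changed genes (2084 higher, 2839 lower). Requiring a 2-fold change on the log2(FPKM + 1) scale left 840 (398 and 442). Library weights gave 9356 (3904 and 5452), and a mean of at least 5 FPKM, which tests fewer genes, gave 1332 higher. Leaving out each library in turn gave 3020 to 5436 changed, 1223 to 2178 higher, 1759 to 3258 lower and 21 to 25 called lists. With the adipose list as a covariate, limma called 0 genes (0 higher, 0 lower; 1953 at an unadjusted p under 0.05), where the covariate correlated with the group at 0.8965 over the 6 libraries, and log2 fold changes correlated with the reported ones at 0.9126 across genes, which are not independent. With an estimated correlation camera called 0 lists. The share of calls that were higher was 42.3%, and 49.6% with median-of-ratios scaling, 49.4% with quantile normalization and 36.4% with equal totals. Limma voom called 4914 genes and kept 95.1% of the calls.

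The Rptor level, as a log2 fold change, was −0.4538 without a filter (adjusted p = 0.076) and missed the 2-fold limit at −0.4538. It was −0.2356 with the adipose covariate (adjusted p = 0.74) and −0.5365 to −0.3517 with each library left out, where adjusted p-values ranged from 0.026 to 0.10. For library similarity, the mean correlation within groups minus that between groups was 0.0454, and 0.0168 without a filter, 0.0653 at a mean of at least 5 FPKM, 0.0608 with voom and 0.0377 to 0.0568 with each library left out.

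Medians of 7 lists changed sign besides that of the adipose list. Glandular epithelium (0.0111) went to −0.0053 with a pseudocount of 5, −0.0342 with equal totals, −0.0482 with quantile normalization, between −0.0262 and 0.187 with each library left out and −0.1395 with the adipose covariate. Wnt signalling (0.0039) went to −0.0163 at a mean of at least 5 FPKM, −0.0518 with equal totals, −0.1163 with library weights, −0.0317 with the adipose covariate and between −0.1723 and 0.118 with each library left out. Interferon response (0.0783) went to −0.0365 with library weights, −0.0700 with the adipose covariate and between −0.0517 and 0.1585 with each library left out. Transport (−0.1894) went to 0.0022 without a filter and 0.0323 with library weights, neutrophil markers (−0.7235) to 0.0427 and 0.5231 under the same settings and between −1.1862 and 0.0619 with each library left out, mesothelium (0.3289) to −0.0246 with library weights and mTORC1 components (−0.1116) to 0.0171 with quantile normalization. With the adipose covariate Cfd went to −0.1492, Cidec to −0.1678, Krt5 to −1.348 and the adipose list, from which the covariate was made, to −0.1585. For the other changes the cause was not tested.

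With the replicate block, 4774 genes were called (2044 higher, 2730 lower), as were the lymphatic (4 rose, adjusted p = 0.013) and luminal (adjusted p = 0.043) lists, and 23 matrix genes rose. Deviations of same-numbered libraries correlated at −0.2024, 0.499 and 0.1444, so the numbers were not taken to be paired, and 3 of 6 libraries correlated best with their own number.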

Other observations

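The tests of the cholesterol pattern, of the cell type mix, of scaling as the whole cause and of a shared rise of 5' TOP transcripts, of a wrong label and of epithelium as the whole cause were chosen after the results were seen, as were the gene lists and genes added here. Several groups of genes of protein turnover and translation were lower in the Rptor cKO. Of 37 proteasome subunits 32 fell and 0 rose (median −0.70), with Psmb5 from 203 ± 23.4 to 98.7 ± 12.7 FPKM (limma adjusted p = 0.0017). Cytosolic aminoacyl-tRNA synthetases, some of which are also in the ATF4 list, fell in 17 of 19 cases (median −0.70), with Aars from 28.8 ± 1.24 to 11.1 ± 1.46 FPKM (adjusted p = 0.00066). Translation factors not classed as 5' TOP fell in 21 of 26 cases (median −0.53) and CCT chaperonin subunits in 7 of 8 (median −0.46). The camera adjusted p was 8.3e-11, 8.7e-08, 6.2e-08 and 0.0017 for these 4 lists, and the adjusted p was 0.37, 0.11, 0.30 and 0.37 with an estimated correlation. Mitochondrial ribosomal proteins fell in 68 of 78 cases (median −0.50), or 43 without control replicate 3, mitochondrial import genes in 17 of 23 (median −0.48), or 11 without that library, and mitochondrial tRNA synthetases in 6 of 17 (median −0.23), or 3 without it. Their camera adjusted p was 2.2e-13, 2.9e-05 and 0.012, and the adjusted p was 0.37, 0.37 and 0.39 with an estimated correlation. None of the 13 transcripts encoded in mitochondrial DNA passed in limma (median 0.12, camera adjusted p = 0.17). For the groups that fell, a smaller share of epithelium was not tested as a source. General epithelial markers fell by a median of −0.57 in the same libraries.

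Cornified envelope and squamous genes, among them Sprr2 genes also in the estrogen list, fell in 8 of 14 cases and rose in 1 (median −1.92, camera adjusted p = 0.0011, adjusted p = 0.39 with an estimated correlation). The number that rose was 2 without Rptor cKO replicate 3 and, at the limma threshold, 0 without control replicate 1, control replicate 3, Rptor cKO replicate 1 or Rptor cKO replicate 2. Il36a, an epithelial cytokine gene, dropped from 21.5 ± 3.30 to 1.74 ± 1.299 FPKM (adjusted p = 0.00081) and Serpinb5 from 7.36 ± 0.96 to 0.757 ± 0.25 FPKM (adjusted p = 0.00034). Complement genes rose in 9 of 16 cases and fell in 1 (median 0.51, camera adjusted p = 0.0098, adjusted p = 0.37 with an estimated correlation), and 5 rose without control replicate 1 or Rptor cKO replicate 1 and 2 without control replicate 3. Without control replicate 2 or Rptor cKO replicate 3, 2 complement genes fell. Subunits of the vacuolar ATPase rose in 5 of 19 cases and fell in 1 (median 0.21, camera adjusted p = 0.030, adjusted p = 0.41 with an estimated correlation), and 3 rose without control replicate 3, Rptor cKO replicate 1 or Rptor cKO replicate 2 and 8 without Rptor cKO replicate 3. The number that fell was 0 without control replicate 3. Host genes of small nucleolar RNAs rose in 3 of 7 cases and fell in 1, or 2 without Rptor cKO replicate 3 (camera adjusted p = 0.26 with all libraries), and 2 of 9 histone genes fell (camera adjusted p = 0.28), or 4 without Rptor cKO replicate 3.

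All 25 members of the cholesterol synthesis list fell. A smaller share of epithelium as the whole source is argued against by the change of the cholesterol list mean, which differed from that of the epithelial list by −1.3854 log2 units (largest group SD 0.2174). Other scalings moved the list median by at most 0.0587, which argues against scaling. The Rptor cKO library with the lowest adipose level, replicate 2, had 96.1% of the mean fall of the other libraries. Its adipose list mean still lay 1.24 log2 units above the control mean. This single library therefore cannot exclude a contribution of RNA from adjacent fat. The activity of SREBP2 was not measured, and no biological explanation was tested beyond the genotype that the design names.

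Ribosomal protein transcripts rose, while translation factors not classed as 5' TOP fell in 21 of 26 cases. Genes matched on length and abundance had a median of −0.1037 (highest of 100 draws −0.0707), which argues against length and abundance as the source. Those translation factors had a median of −0.5283 with a 75th percentile of −0.3918, which argues against a general rise of translation genes. The bound set for that rise also required the other 5' TOP genes to exceed 0.2667. Their median was 0.1296, so this part of the bound was not met. It is a condition on another list that a general rise of translation genes does not need. Scaling may set part of the size, since the median moved by up to 0.3009, yet at least 42 of 81 genes rose under each of 3 other scalings. A change in the mix of cell types stays open, with endothelium up by 1.0192 and the lowest endothelial and ribosomal protein levels in the same library in both groups. A shared rise of 5' TOP transcripts stays open too: 8 of 20 non-ribosomal members rose and 2 fell (median 0.1296, camera adjusted p = 0.019, adjusted p = 0.39 with an estimated correlation; 4 rose and 0 fell without Rptor cKO replicate 1, 5 rose and 1 fell without Rptor cKO replicate 2 and 1 fell without control replicate 3), among them Eef1a1 from 4850 ± 403 to 10426 ± 349 FPKM.

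Rptor cKO replicate 3 had proliferation genes nearer to control than the other Rptor cKO libraries. A wrong label is argued against by its cholesterol list mean, 1.91 below control (−1.9067), and admixed control RNA by the 95.6% of the cholesterol change that it had, beside 21.4% of the G2/M change. A larger share of epithelium may contribute, since its epithelial list lay 0.2242 above the higher of the other Rptor cKO libraries, which differed by 0.1846. As the whole source it is argued against by the G2/M list, which lay 1.3545 above. A difference between animals in the timing of the response was not tested.

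In the 10 splits of the 6 libraries into groups of 3, only 1, the real one, gave as many changed genes (4923, highest other 0), as many higher (2084, highest other in either direction 0) or as many lower (2839, highest other 0), and 3 gave as many called lists (23, highest other 26). With 10 splits the share cannot be under 0.05. Each other split mixes the genotypes, which widens the spread within its groups. The 0 changed genes of these splits therefore do not measure chance. The mixed splits called 7 to 26 lists, so the number of called lists did not set the real split apart.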
